A study of Homo sapiens with 6 samples.

How the data were processed

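Total RNA of 6 samples of the HT29 line, 3 sensitive and 3 resistant to methotrexate, was labelled with Cy3 and hybridised to single-colour Agilent miRNA arrays, per the labels. The RNA kit, per the labels' protocols, was the Real Total microRNA kit. Each deposited file holds 1 array's total signal per miRNA as a background-subtracted intensity on a linear scale, its error and a detected flag, per the file headers. Of 821 features, 799 were miRNAs and 22 were controls, which were left out of all tests. The version of the extraction software, the scanner and the scan dates are not given in the sources used here, so arrays could not be assigned to scan batches. The deposited value table of the series held intensity values identical to the scanner signals (largest difference 0), with medians over miRNAs of 0.53, -7.52, 1.54, -1.44, -2.22 and 2.00 for sensitive 1 to 3 and resistant 1 to 3. Its scale and direction are therefore those of the linear signals, with no centring. The series design names GeneSpring GX 11.5 for the submitters' own analysis, whose output was not used here.

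Groups and replicate numbers were taken from the labels. Nothing in them says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The median error of a signal was 14.5, 29.7 and 10.8 brightness units on the sensitive and 12.0, 21.7 and 11.5 on the resistant arrays, largest on both arrays numbered 2.

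Signals were divided by each array's 75th percentile over the 81 miRNAs detected on all 6 arrays and multiplied by the geometric mean of the 6 percentiles. Scaled signals below 33.1, the median over arrays of the lowest scaled detected signal, were set to that floor before log2 was taken, so fold changes of dim miRNAs are understated. A miRNA was tested when detected on all 3 arrays of at least 1 group, which left 93. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Where every array of a group failed detection, a bound was set from the mean log2 signal of the bright group against, per array, the higher of the lowest detected signal and the miRNA's own. A signal above an array's lowest detected one could still fail detection, so this bound is not strict. Scaled means ± SD are given before the floor, and folds come from the log2 differences.

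Fixed before the data were examined were the design, most alternatives, 27 miRNA lists and a naming rule. The rule takes miR-224 and miR-452, then up to 12 miRNAs per direction with the largest differences among those past the threshold whose groups do not overlap. It adds list members past the threshold and miRNAs detected on all arrays of 1 group and none of the other. The lists cover miRNA families and genomic clusters, intestinal epithelium, regulators of folate enzymes, colorectal tumours, markers of stromal, blood and endothelial, muscle, neural and hepatocyte cells, and viral miRNAs. Lists with at least 3 tested members, 10 in all, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. In the lists on which no sentence of the results dwells, the miR-30 family (3 tested), the miR-34 and miR-449 family (1), the Xp11 cluster (1) and the 14q32 cluster (1) had no member past the threshold. The miR-183 cluster had 1 tested member, miR-183, which fell. The result of 1 further list is not reported here. Of the 76 viral miRNAs, 10 were detected on any array and 0 were tested.

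The replicate numbers are shared between the groups. Deviations from the group means over the tested miRNAs correlated at 0.40, 0.28 and 0.69 for the pairs numbered 1, 2 and 3, each above 0.1, so the numbers were taken to pair the samples. This pairing comes from the data, as the labels give no reason for it. It is not settled: sensitive 1 with resistant 2, of unlike number, also exceeded 0.1, at 0.20. The other pairs of unlike number ranged from -0.51 to -0.01. Deviations of 3 arrays from their mean sum to 0, so these correlations depend on each other.

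Alternatives were the percentile over all miRNAs, quantile normalization, no scaling, median centring, the deposited value table, other floors, other detection filters, an intensity trend, no variance moderation, a 2-fold threshold, the replicate number as a block, and leaving out each array. At most 137 of the 799 miRNAs were detected on a single array, so the percentile over all miRNAs lay at the level of undetected signals. No scaling left differences in brightness between arrays in the values. Leaving out both arrays numbered 2, the estimated correlation, sign flips of the paired counts of detected miRNAs, the highest floor for miR-452 and the block joined to a stricter filter were chosen after seeing the data. Camera was not run without variance moderation. Genomic neighbours were found in a RefSeq table of assembly GRCh38.p14, used for names and neighbours only, in which 91 of the 93 tested miRNAs were matched. Permutations were run in Python 3.11.15.

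The test was tested on simulated data with 93 tested miRNAs, 8 changed per fold size and 50 simulations of the comparison of resistant with sensitive cells. It recovered 46.2% of changes of 1.5-fold, 87.4% of 2-fold and 100% of 4-fold. Of its calls 10.3% were false, above the nominal 5%, against 3.27% when the arrays needed no scaling. The let-7 list, with 9 tested members all shifted 2-fold, was recovered in 100% of simulations, and 4.6% of unshifted lists had p under 0.05. Noise was drawn independently for each miRNA, so neither share covers lists of correlated members. Recovery of lists with fewer members or smaller shifts was not simulated. The permutation of neighbours, in 40 simulations on 93 miRNAs, had p under 0.05 in 5% without and 100% with a shared change. Changes without a shared part were shuffled as the test itself shuffles them, so a share near 5% was fixed in advance. The shared change was set well above the noise, so recovery of weaker sharing is unknown.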

Results

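The study compared 2 forms of HT29, a human colorectal adenocarcinoma cell line: cells sensitive to methotrexate, and cells resistant to it at a concentration written as 10e-5 M in the series design. Methotrexate is an antifolate drug. Each form was measured on 3 single-colour Agilent microRNA arrays carrying 723 human and 76 viral miRNAs. The software called 104, 109 and 137 miRNAs detected on the sensitive arrays and 101, 92 and 126 on the resistant arrays. The means, 117 ± 17.8 and 106 ± 17.6 (SD, n = 3), differed by less than the spread between arrays (exact permutation test, two-sided p = 0.5, the smallest possible p being 0.1). The difference of -10.3 rested on single arrays: it was -0.17 without sensitive 3, -3.17 without resistant 2, -16.7 without sensitive 1 and -20.2 without resistant 3, and -3.33 when a signal over 3 errors stood for the flag. The resistant array had fewer in each of the 3 pairs of the same number, by 3, 17 and 11 (exact sign-flip test, p = 0.25, the smallest possible). In all, 81 miRNAs were detected on all 6 arrays and 626 on none. Pearson correlations of log2 signals, across the 93 miRNAs tested, were 0.971 to 0.991 between arrays of 1 group and 0.889 to 0.931 between groups. These are correlations across miRNAs, which are not independent replicates. No value was identical between any pair of arrays.

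The series title names miR-224, a miRNA encoded in an intron of GABRE, as underexpressed in the resistant cells, and its level was compared first. The scaled signal of miR-224 was 1398 ± 60.0 in sensitive and 134 ± 45.1 in resistant cells (SD, n = 3), a 10.9-fold lower level in the resistant cells. It was detected on all 6 arrays, and each resistant array lay below each sensitive one. The log2 difference, resistant minus sensitive, was -3.45 (SE 0.27, 95% confidence interval -4.08 to -2.82; limma adjusted p = 7.81e-05). Testing all 799 miRNAs without a detection filter ended this call, at a limma adjusted p of 0.0511 with the same difference. That fit took in 626 miRNAs detected on no array, and limma's prior degrees of freedom fell from 3.39 to 0.07. The loss of a call in that fit therefore reflects the added features as well as the miRNA itself. miR-452, encoded in the same host gene, was detected on 2 sensitive arrays and on no resistant array, with scaled signals of 101 ± 30.8 and 1.67 ± 19.9 (SD, n = 3). It did not meet the detection filter and was not tested there. With miRNAs detected on at least 1 array admitted, the fit, with all resistant arrays at the common floor, gave a log2 difference of -1.56, or 2.94-fold (limma adjusted p = 0.0248). With the highest floor the difference was -0.98 and the call was lost (limma adjusted p = 0.114). Against each resistant array's own lowest detected signal, lowest on resistant 3, miR-452 was 3.18-fold lower in resistant cells, its undetected sensitive signal taken as measured. That is not a strict lower bound. Its sensitive signals, 67.3 to 127, all exceeded the lowest detected signals of those arrays, 20.3 to 36.3, yet not all were detected.

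Among the miRNAs higher in resistant cells, miR-210, a miRNA induced by hypoxia, had the largest measured difference. Its scaled signal was 71.6 ± 28.5 in sensitive and 795 ± 154 in resistant cells (SD, n = 3), an 11.7-fold difference (log2 3.55, SE 0.33, limma adjusted p = 1.93e-04). miR-149 rose 7.13-fold, from 76.2 ± 5.41 to 553 ± 136 (SD, n = 3; limma adjusted p = 5.93e-05). Both were detected on 2 of 3 sensitive arrays. Without a detection filter miR-210 lost its call (limma adjusted p = 0.0909) and miR-149 kept its own (limma adjusted p = 0.0431). miR-193b and miR-365, which are encoded side by side at 1 of the 2 copies of miR-365, rose 4.54-fold and 3.51-fold (limma adjusted p = 0.00156 and 1.93e-04). Both lost their calls without a detection filter (limma adjusted p = 0.230 and 0.0511). miR-505 was not well above background on any sensitive array and was detected on all 3 resistant arrays, at 176 ± 20.5 (SD, n = 3). Against each sensitive array's own lowest detected signal it was 6.26-fold higher in resistant cells, which, as for miR-452, is not a strict lower bound. The fit with the common floor gave 5.30-fold (limma adjusted p = 3.27e-05), and the highest floor a log2 difference of 1.83. The number of miRNAs with the opposite pattern was 0 (5 when sensitive 2 was left out).

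Of the 93 miRNAs tested, 28 differed between the lines, 14 higher and 14 lower in resistant cells (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 38. The values of the 2 groups lay apart for each of the 28, and for 44 of all 93 tested (47.3%, against 10% by chance). Of the 28, 10 were at least 2-fold higher and 4 at least 2-fold lower. Further miRNAs that rose were miR-27b (2.64-fold), miR-320 (2.49-fold), miR-361-5p (2.44-fold), miR-455-3p (2.39-fold) and miR-378 (2.05-fold, a call lost without scaling). Each of these calls was lost without a detection filter (limma adjusted p from 0.0511 to 0.391). miR-615-3p rose from 19.1 ± 3.26 to 54.7 ± 0.66 (SD, n = 3). It was detected on 1 of 3 sensitive arrays, and its call was lost with the floor at the highest, over arrays, of the lowest detected signals, and without scaling (log2 difference 0.82, limma adjusted p = 0.186). Further miRNAs that fell were miR-183 (1.79-fold), miR-425 (1.79-fold), miR-151-5p (1.62-fold) and miR-22 (1.54-fold), with limma adjusted p of 0.0368, 0.0397, 0.0144 and 0.0195. All 4 calls were lost without scaling and with the percentile over all miRNAs, and when 1 array was left out the first pair passed in 2 of 6 fits and the second in 4. The remaining call, miR-151-3p, lay outside the naming rule and is named after its values were seen.

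**Figure D1:**
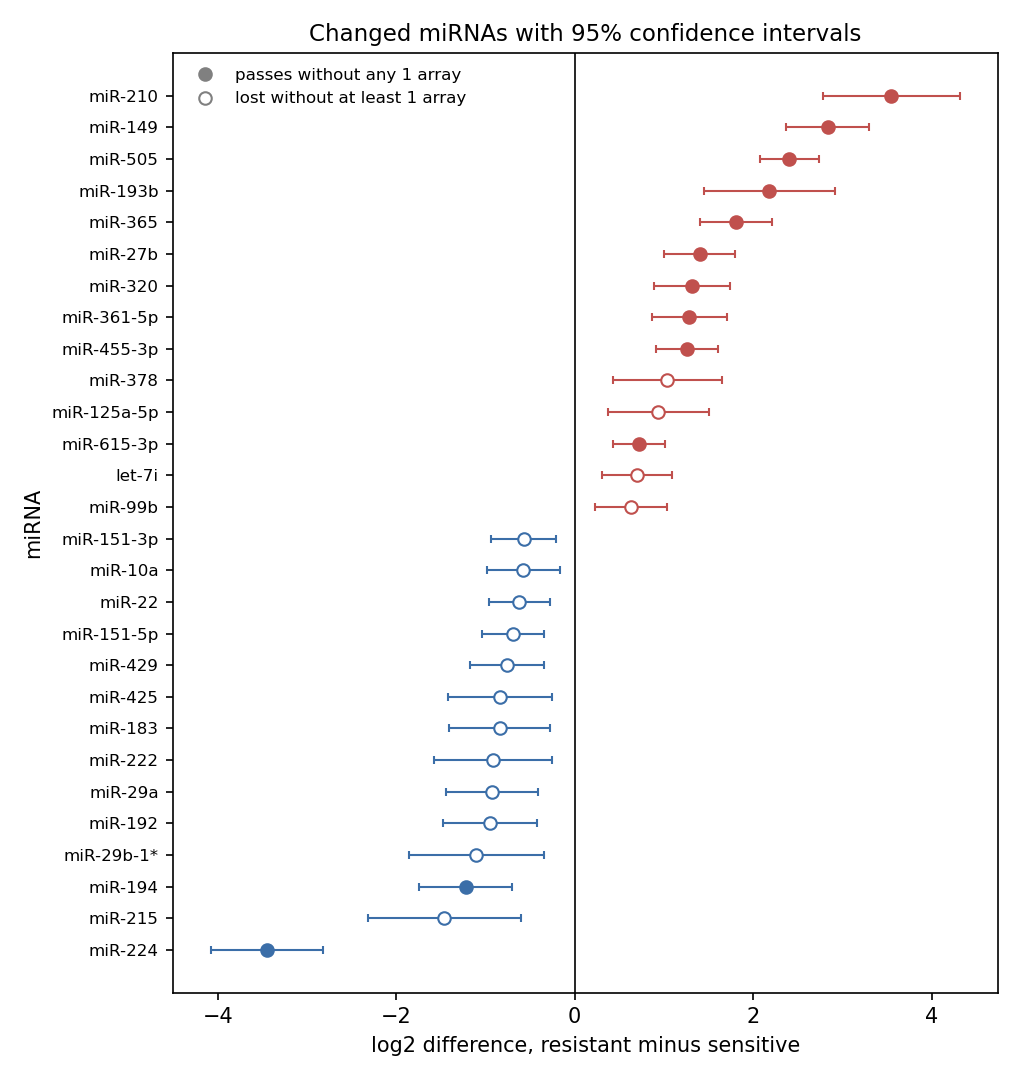
Log2 difference, resistant minus sensitive, of each of the 28 changed miRNAs (points) with its 95% confidence interval (bars), red for higher and blue for lower in resistant cells. Filled points, 12 in number, passed in all 6 fits that left out 1 array; open points, 16 in number, did not.

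Of the list of miRNAs abundant in intestinal epithelium, 5 were on the arrays, 4 were detected on any array and 3 were tested. All 3 tested members were lower in resistant cells and passed the test, over all miRNAs and adjusted over the list alone, and under each scaling. When 1 array was left out, miR-194 passed in all 6 fits, miR-192 in 2 and miR-215 in 1. miR-192 and miR-215 also lost their calls without variance moderation (limma adjusted p = 0.0789 and 0.115) and with miRNAs detected on at least 1 array (0.0756 and 0.112), and all 3 members lost theirs without a filter and without both arrays numbered 2. miR-194 fell from 656 ± 24.1 to 290 ± 92.7 (SD, n = 3; log2 difference -1.22, SE 0.22, limma adjusted p = 0.00602). miR-215 fell 2.75-fold (limma adjusted p = 0.0223) and was detected on 1 of 3 resistant arrays, and miR-192 fell 1.93-fold (limma adjusted p = 0.0195). As a set they did not pass the camera test (p = 0.0196, adjusted p = 0.196 over 10 lists; adjusted p = 0.646 with an estimated correlation). miR-192 and miR-215 are also 2 of the 3 tested members of the list of regulators of folate enzymes, where the third, miR-24, had a log2 difference of -0.10 (limma adjusted p = 0.67). Of the miR-29 family, which represses collagen genes, only miR-29a was tested, with a log2 difference of -0.92 (limma adjusted p = 0.0195), a call lost without scaling and in 3 of the 6 fits without 1 array. miR-29b-1*, the opposite arm of a family hairpin and in the same list, had a log2 difference of -1.10 (limma adjusted p = 0.0392) and passed in 1 of those 6 fits. In the miR-99 and miR-125 families both tested members rose (1 with median centring, 0 without scaling), miR-125a-5p by 1.91-fold and miR-99b by 1.55-fold (limma adjusted p = 0.0242 and 0.0299). They passed in 2 and 1 of the 6 fits without 1 array, and neither passed without variance moderation or with miRNAs detected on at least 1 array.

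**Figure D2:**
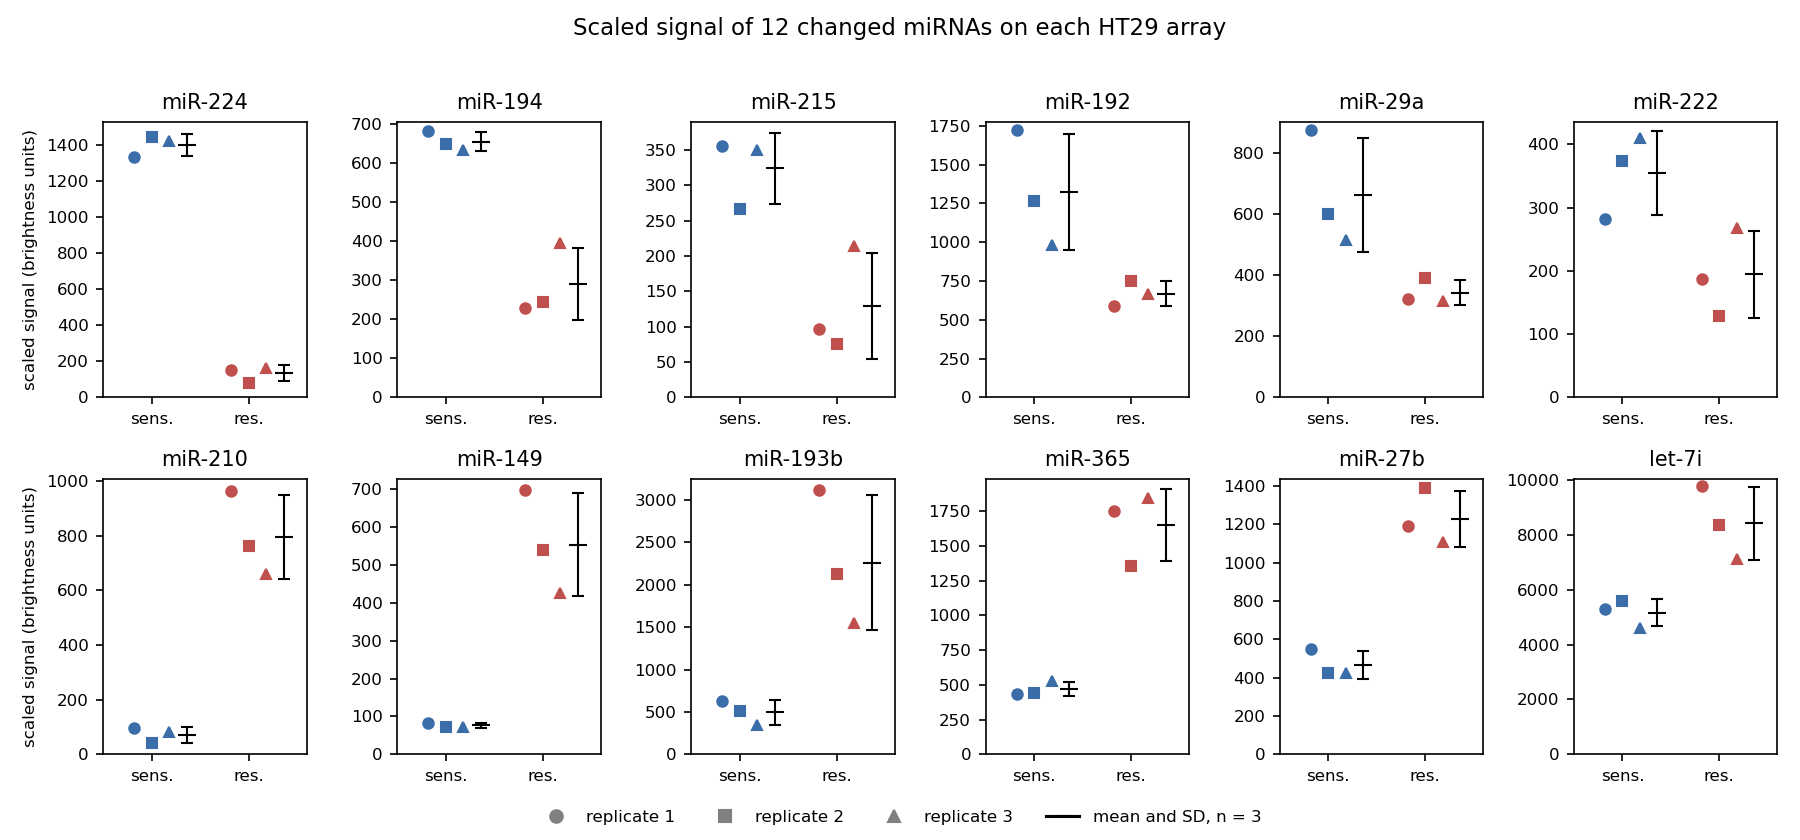
Scaled signal, in brightness units on axes that start at 0, of 12 changed miRNAs on each sensitive (sens., blue) and resistant (res., red) array, with symbols for replicates 1 to 3. Black bars give the mean and SD of 3 arrays; miR-224 lies at 1398 ± 60.0 in sensitive and 134 ± 45.1 in resistant cells.

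In other families single members changed. Of 5 tested members of the miR-200 family, which represses ZEB1 and ZEB2, miR-429 fell 1.69-fold (limma adjusted p = 0.0195) and 4 did not pass, nor did the opposite arm miR-200b* of the same list. In that list 3 passed as lower with median centring and 0 without scaling or with the percentile over all miRNAs. miR-222, which represses CDKN1B, fell 1.88-fold (limma adjusted p = 0.0442), while its cluster partner miR-221 had a log2 difference of 0.23 (limma adjusted p = 0.368); the call on miR-222 was lost without scaling and in 5 of the 6 fits without 1 array, with adjusted p up to 0.258 and a log2 difference of -0.65 without resistant 2. Of 5 tested members of the clusters of miR-23, miR-24 and miR-27, only miR-27b passed (2 passed with quantile normalization), and of 4 tested miRNAs encoded in HOX clusters only miR-10a, with a log2 difference of -0.58 (limma adjusted p = 0.042), a call lost without scaling and with the percentile over all miRNAs. In the let-7 family, let-7i rose 1.62-fold (limma adjusted p = 0.0198) and the other 8 tested members did not pass, except 1 as lower with median centring and 1 in each direction with quantile normalization; without scaling none passed. With the array number as a replicate block, let-7e also passed as higher (log2 difference 0.55, limma adjusted p = 0.0129) and let-7b and let-7d as lower (log2 differences -0.34 and -0.42, limma adjusted p = 0.0446 and 0.0351). In the same blocked fit miR-15b of the miR-15 and miR-16 family, miR-181a of the miR-181 family and miR-31* of the colorectal tumour list passed, where at the same scaling no member of these lists passed without it. With other scalings, 1 miR-15 and miR-16 member passed as higher (percentile over all miRNAs), 1 miR-181 member as lower (median centring) and, of the colorectal list, 1 in each direction with quantile normalization and 1 as lower with median centring. None of the 8 tested members of the miR-17 and paralogous clusters, known for their part in proliferation, passed, though 1 did as lower with median centring. All 8 had negative log2 differences, from -0.41 to -0.01, but 2 of them turned positive with the percentile taken over all miRNAs and 1 with quantile normalization. By limma's camera test 0 of the 10 lists with at least 3 tested members passed, and 1 had an unadjusted p under 0.05.

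Markers of other cell types were scarce on these arrays. No miRNA of the stromal, blood and endothelial, or muscle lists, nor of the placental chromosome 19 cluster, was detected on any array. Of the neural list only miR-128 was detected, on 2 arrays of each group, and the hepatocyte miRNA miR-122 was detected on 2 resistant arrays, at 69.3 ± 33.1 against 10.3 ± 14.1 in sensitive cells (SD, n = 3). None of these was tested.

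**Figure D3:**
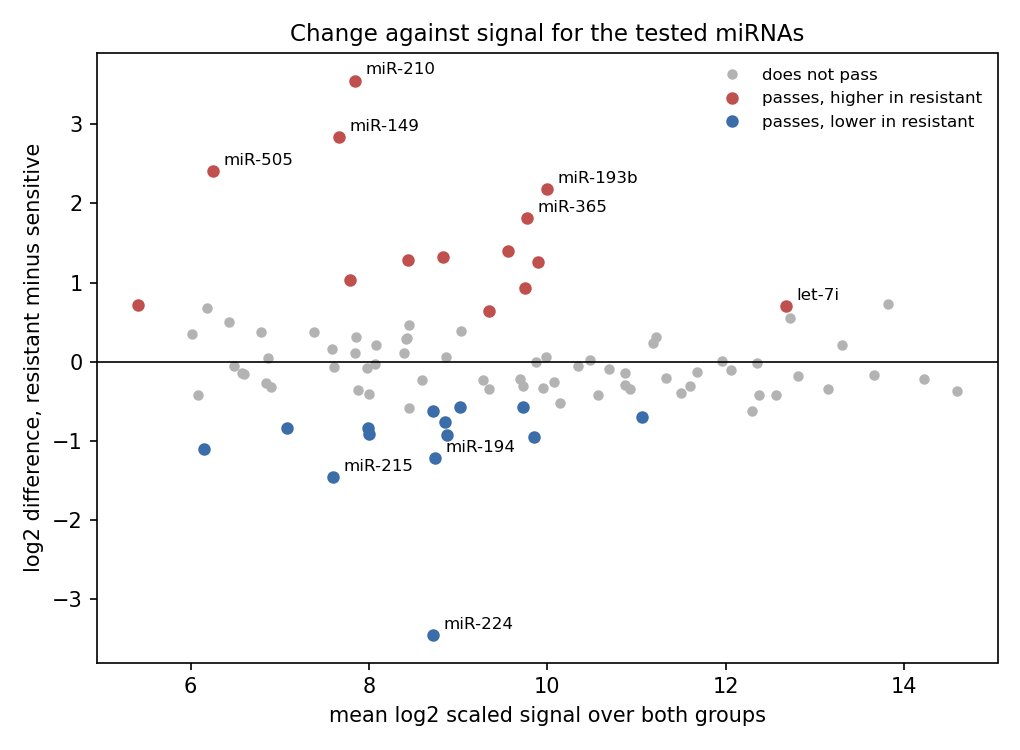
Log2 difference, resistant minus sensitive (vertical axis), against the mean log2 scaled signal over both groups (horizontal axis) for the 93 tested miRNAs (points), grey where the test was not passed. The 14 higher (red) and 14 lower (blue) miRNAs include miR-224 at -3.45 and miR-210 at 3.55.

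The balance of 14 higher and 14 lower depended on the scaling: it was 16 and 7 with the percentile over all miRNAs, 9 and 5 without scaling and 13 and 22 with median centring, which moved the median log2 difference of all tested miRNAs by 0.16, -0.16 and -0.17 from its value of -0.10. Quantile normalization gave 17 and 16, kept all 28 calls and moved that median by 0.05. Of the 28 calls, 12 passed in each fit that left out 1 array: miR-224 and miR-194 among the lower, and miR-210, miR-149, miR-505, miR-193b, miR-365, miR-27b, miR-320, miR-361-5p, miR-455-3p and miR-615-3p among the higher. All lower calls of a fit, whether among the 28 or not, numbered 2 without sensitive 1, 6 without sensitive 2, 9 without sensitive 3 or resistant 1, 5 without resistant 2 and 15 without resistant 3. Of these, 3 of the 6 without sensitive 2 and 10 of the 15 without resistant 3 were among the 28. In the other fits all were. Of the other 16 among the 28, miR-151-5p and miR-22 passed in 4 of these 6 fits, miR-29a, miR-378 and miR-429 in 3, and let-7i, miR-125a-5p, miR-151-3p, miR-183, miR-192 and miR-425 in 2. miR-10a, miR-99b, miR-215, miR-222 and miR-29b-1* passed in 1. Without variance moderation 14 of these 16 calls were lost, all but miR-151-5p and miR-22.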

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

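The tests of the 28 changed miRNAs, of the lists and of viral RNA in the sensitive cells were chosen after those results were seen. The test of the viral share was set before its own result, but after the viral calls had been seen. For changes under 2-fold, a further count, of changes that under all other scalings stayed larger than the margin of the first fit's 95% interval, gave 14 of 14; it was written with these sizes in view and takes the smaller spread, so nothing rests on it.

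For the 28 miRNAs past the threshold, the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 28 calls and the highest of the other splits 1. For lists the real split gave 0 and the highest other 1, with 10 of 10 splits giving at least as many. That count was fixed in advance, as no split can give fewer than 0 lists, so it decides nothing. If the numbers are taken to pair the samples, 4 splits part all 3 pairs, and the 3 other than the real one gave 0 calls. An offset particular to this scaling is argued against for changes of at least 2-fold, of which 13 of 14 passed under each of the 4 other scalings. Those scalings moved the median log2 difference of all tested miRNAs by at most 0.17. An offset shared by all of them was therefore not tested. For the smaller changes an offset stays open, as 1 of 14 passed under each (14 with quantile normalization, 13 with median centring, 7 with the percentile over all miRNAs and 1 without scaling). All 14 kept their direction, and most calls ended as the median SE rose from 0.18 to 0.29 with the percentile over all miRNAs and 0.41 without scaling, where the median size went from 0.74 to 0.71 and 0.84; the 7 lost with that percentile were all lower ones, which it also moved toward 0 by 0.16. That percentile lay at the level of undetected signals, and no scaling left differences in brightness between arrays in place. Calls lost under either setting therefore cannot decide whether an offset was left. Differences shared by arrays of 1 number cancel from the comparison by design, each number having 1 array per group; the difference between the lines stays open as a biological explanation, and whether any handling differed between the lines was not tested.

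A control feature that the files call hur_4 was 1.77-fold brighter, after scaling, on resistant arrays, at 39077 ± 5029 against 22026 ± 3254 (SD, n = 3), with each resistant array above each sensitive one (exact permutation p = 0.1, the smallest possible). It was picked by this separation among controls detected on all 6 arrays, so the p tests nothing further. The other controls detected on all 6 arrays were 1.08-fold to 1.46-fold brighter on resistant arrays after scaling (exact permutation p = 0.3 to 0.7). Before scaling, hur_4 had means of 24279 on sensitive and 39568 on resistant arrays. Most of the others were nearly equal then: 75801 and 75723 (hur_1), 80124 and 79682 (hur_2), 26319 and 26981 (hur_6) and 48770 and 47980 (mr_1). The exception was miRNABrightCorner30, at 4008 and 5198. What hur_4 binds is not given in the sources used here.

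On the sensitive array numbered 2, 8 viral miRNAs were called detected that were detected on no other array, with signals of 43.1 to 200.5 brightness units. Of these, 3 exceeded 3 times their error there. For them viral RNA shared by the 3 sensitive samples at that array's level is argued against. All 3 fell short of its scaled level by over 2 combined errors on both other sensitive arrays. The choice of calls made on no other array dropped none, as all 8 viral calls of this array were its own. But the 3 were chosen as bright on this array, so their level there may be overstated, and shared viral RNA at a lower level stays open. For the other 5, under 3 errors on the array that called them, shared viral RNA stays open, with 3 of 5 falling short by as much. Viral RNA in that sample alone was not tested. Sensitive 3 and resistant 3 each had 1 viral call of their own, of other miRNAs at 42.5 and 43.6 brightness units. A random pick among dim features at this array's high background was set against the viral share. Of 23 miRNAs detected on this array alone 34.8% were viral, against 11.4% of the 649 detected on no other array (exact hypergeometric p = 0.00234). The array and the viral group were picked on seeing these 8 calls, so this p does not decide whether the pick was random. Features were treated as independent there, and a flaw over part of the array stays open, since the files give no positions; no biological explanation beyond viral RNA was tested.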

How the results depend on the processing

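miR-224 stayed lower in resistant cells under every alternative run, with log2 differences from -3.63 to -2.95; it lost its call only without a detection filter (-3.45, limma adjusted p = 0.0511, in a range over alternatives from 3.79e-24). Without a filter the prior degrees of freedom of limma fell from 3.39 to 0.07. Without scaling and with the percentile over all miRNAs they were infinite, so all miRNAs shared 1 spread and the smallest p-values rest on that. Leaving out 1 array gave -3.63 to -3.13 for miR-224, with adjusted p up to 0.00261. Against 28 changed miRNAs (14 higher, 14 lower), there were 14 (9 and 5) without scaling and 3 (3 and 0) without a filter. Those 3 were miR-149, miR-505 and miR-615-3p. On the sensitive arrays every value of miR-505 and miR-615-3p was set to the floor, with a log2 SD of 0, so passing there does not make them sturdier than miR-224. There were 17 (12 and 5) without variance moderation and 14 (10 and 4) with a 2-fold threshold. The lower count was also 7 with the percentile over all miRNAs and 22 with median centring. Quantile normalization gave 33 (17 and 16), with all 28 calls among them. Leaving out 1 array gave 13 to 30 changed miRNAs, 10 to 15 higher and 2 to 15 lower: in total 13 without sensitive 1, 18 without sensitive 2, 20 without sensitive 3, 19 without resistant 1, 19 without resistant 2 and 30 without resistant 3. The lower count was 2, 6, 9, 9, 5 and 15 in that order, of which 2, 3, 9, 9, 5 and 10 were among the 28. Without both arrays numbered 2, chosen after seeing the data, 16 miRNAs changed (12 and 4), of which 12 (11 and 1) were among the 28. For the 28 calls the highest adjusted p over these 6 fits was 0.0628 to 0.258 in the 16 that were lost in at least 1 of them. The other 27 calls kept their direction over 555 recomputed values, of which 150 no longer passed. With the replicate block for the paired numbers, 36 miRNAs changed (18 and 18): all 28 passed, with miR-224 at -3.45, and 8 more did, namely let-7b, let-7d, let-7e, miR-15b, miR-181a, miR-185, miR-31* and miR-324-5p; it changed no other call. The count of lists past the threshold was 0, except 1 without a filter and 0 to 1 when 1 array was left out. The list without a filter was the miR-224 host locus (adjusted p = 0.0105, or 0.505 with an estimated correlation), and that without resistant 3 was intestinal epithelium (adjusted p = 0.0434, or 0.734 with an estimated correlation). The miR-15 and miR-16 list's median turned from 0.11 to -0.05 without scaling, -0.06 with median centring and -0.04 without resistant 2, and the colorectal list's from -0.26 to 0.04 without both arrays numbered 2. 1 miRNA was detected on all resistant and no sensitive arrays, 2 when a signal over 3 errors stood for the flag and 1 to 2 without 1 array; the opposite count was 0, and 0 to 5 without 1 array (5 without sensitive 2). Apart from miRNAs tested or arrays fitted, the cause was not tested.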

Other observations

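All tests of neighbouring miRNAs were chosen after the changes of the miRNAs had been seen, and the interval on the family difference after its mean. Star arms, which carry another seed than the opposite arm, were at first counted in its seed family and were given their own after these results had been seen.

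Many miRNAs encoded close together had similar log2 differences, with exceptions. miR-193b and miR-365 had log2 differences of 2.18 and 1.81, miR-192 and miR-194 of -0.95 and -1.22, and let-7e, miR-99b and miR-125a-5p of 0.55, 0.64 and 0.94, let-7e not passing without the block. The cluster of miR-23b, miR-24 and miR-27b was an exception, at 0.31, -0.10 and 1.40, and miR-23a and miR-27a (-0.42 and 0.37) and miR-141 and miR-200c (0.32 and -0.18) had opposite signs, as had miR-200b* (0.11) and its neighbours miR-200a and miR-429 (-0.52 and -0.76). Over 27 pairs of 29 tested miRNAs within 10 kb and of different seed families, the mean absolute difference in log2 change was 0.40, against a permuted median of 0.89 (permutation p = 0.0011), and 20 pairs had the same sign. Pairs both near and of 1 seed family, such as miR-221 and miR-222 (0.23 and -0.91), were left out of this set and of the family set below; with them, 40 pairs gave 0.36 (permutation p = 0.0002) and 31 of the same sign. Without the clusters of the miR-17 type, whose members changed little, 18 pairs gave 0.49 (permutation p = 0.0373) and 11 of the same sign. In the set of 27 pairs, miR-365, miR-194, miR-24, miR-19b and miR-92a each have 2 genomic copies, which an array signal does not tell apart. Their changes cannot be assigned to the copy beside the neighbour.

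That neighbours share a transcript was not tested apart from the pattern itself, and stays open. Generally small changes of clustered miRNAs are argued against, since permuting only among miRNAs with a neighbour gave a permutation p of 0.0001, the smallest these permutations can give. A trend of the change with signal is argued against by a permutation p of 0.0015 after its removal, where 16 of the 27 pairs had the same sign. Cross-hybridization between similar sequences stays open: 53 pairs of 1 seed family encoded apart differed by 0.42 on average (permutation p = 0.0012), more than the neighbours, as a cause other than cross-hybridization predicts, but by less than the spread. That excess was 0.02, with a 95% interval of -0.13 to 0.17 from 2000 resamples of pairs treated as independent, and probe sequences were not used here.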
